A study of Homo sapiens with 9 samples.

How the data were processed

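Polyadenylated RNA from HCT116 cells, a human colon cancer cell line, was sequenced after doxycycline treatment at 3 µM. There were 3 groups of 3 libraries each: a control hairpin (shNC) and a pair of hairpins against ZCRB1 (shZCRB1-1 and shZCRB1-2). ZCRB1 encodes a protein of the minor (U12-dependent) spliceosome. Per the labels, libraries were made with a strand-specific kit, and the design text says that the replicates came from independent experiments. Per the submitters' processing notes, cutadapt 2.0, STAR 2.7.1a and the hg38 genome were used. The tool that computed the inclusion levels, and the authors' statistical test, are not given in the sources used here.

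The values analysed were the authors' deposited table of intron inclusion levels. For each intron it gives 3 inclusion levels per group, each between 0 and 1 with 3 decimals, and the class of the intron (minor or major). The same table holds the authors' deposited p-value, FDR and difference in level for each hairpin against shNC. Differences recomputed from the levels lay within 0.00033 of the deposited ones. A level near 0 is read here as an intron that was nearly always spliced out, and a level of 1 as an intron that was retained. This reading cannot hold for all overlapping introns. With shZCRB1-2 a major intron of TMEM41B had a mean level of 0.913, and a minor intron that differs from it by 7 bases had 0.188. Changes in level of overlapping introns may therefore not be changes in retention. The table gives no read counts, so the depth behind each level is unknown and no interval that needs it was computed. The design set a minimum of 10 reads per intron, which could not be applied. The 3 levels of a group carry no replicate number, so single libraries are not named by number. Their numbering in the leave-one-out settings is only their place in the cell. Residuals of levels at the same place in different groups had correlations from -0.003 to 0.01.

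Coordinates are hg38, converted to 1-based positions. Intron numbers are those of the authors' deposited table, for the first transcript it lists for an intron. The place of an intron (coding part or untranslated region) came from GENCODE release 29, of the same assembly. Of 103878 introns, 103501 (99.6%) had both ends at an intron annotated in that release. No genome sequence was used, so the class given in the table replaced a sequence rule for minor introns, as the design allowed. Symbols joined by a comma are overlapping genes, and values for them are uncertain. Gene expression was not analysed here, nor was ZCRB1, which has 0 introns among those analysed.

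Of the 103878 introns, 89477 had all 9 levels (435 minor and 89042 major). Levels were tested as log2(level + 0.01) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, over the 89167 introns whose levels varied. All 9 libraries shared 1 estimate of the spread, with no block. The contrasts were the mean of both hairpins minus shNC, each hairpin minus shNC, and the difference between the hairpins. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Changes on this scale understate those of introns with levels near 0. The tests, lists and the rule for named introns were fixed before the data were examined. The mean-variance trend was a choice the fixed design did not state, made before any call was seen.

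The rule for named introns asked for ZCRB1 first, then the 12 largest rises among minor introns past the threshold, the 8 largest rises among major introns and the 6 largest falls. It also asked for every member of a minor spliceosome list with an intron past the threshold, and up to 3 members of each other list. Parts on rises and falls needed the same direction in both hairpins, and each part took 1 intron per gene. Because limma called no intron over all introns, the threshold used for naming was the authors' deposited FDR under 0.05 in both comparisons. That replacement was made after limma's result was seen; the fixed design foresaw it only for tables without values per library. The count of minor introns among those called higher rests on the same replacement. A limma count adjusted over the minor introns alone was also added after the data were seen.

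Fisher's exact test (two-sided) compared minor with major introns among those called higher. The class median of log2(level + 0.01) was computed per library, minor minus major, and compared between 6 knockdown and 3 control libraries by a two-sided exact permutation test over 84 splits. The median change of minor introns was also set against 10000 random lists of major introns matched on mean level and length; depth could not be matched. The 13 gene lists were tested with camera and fry from limma. Correlations across introns used 100000 permutations. Introns are not independent replicates. These steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

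The limma script was tested on simulated data: of 50 introns changed by each size among 89167, it recovered 0% at a log2 change of 1, 40% at 2, 78% at 3 and 86% at 4. It also made 15 false calls beside 102 true ones (12.8% of calls), a larger share than the threshold of 0.05 allows. By the median of single-intron changes, a simulated class shift of 0.4 was recovered as 0.388, and a shift of 0 as 0.014. By the per-library class median, in a separate simulation, a shift of 0.4 was recovered as 0.345 and a shift of 0 as 0.03. With no simulated shift, 22 of 1000 matched random lists reached the minor median, so a percentile among such lists may leave out part of the chance spread. The simulation was not repeated to test this. Alternatives covered the pseudocount (0.001 and 0.1), a change of at least 0.1 in level, a threshold of 0.01, introns under 3 kb, the fixed list of minor-intron genes and leaving out each library. Added after seeing the data were limma without the trend and with robust empirical Bayes, other scales, a level filter, 1 intron per gene, and major introns alone. Some introns that the rule for named introns takes are not reported here.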

Results

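Intron inclusion levels were measured in HCT116 colon cancer cells carrying a control hairpin (shNC) or either of 2 hairpins against ZCRB1, with 3 libraries per group. ZCRB1 is a component of the minor spliceosome, which removes the small class of minor (U12-type) introns; major introns are removed by the major spliceosome. The series compared knockdown with control cells. ZCRB1 itself was not analysed here, so the knockdown could not be checked. Pairs of libraries within a group had Pearson correlations across introns of 0.986 to 0.988, and pairs from different groups of 0.985 to 0.987. The sequencing depth behind each level is unknown.

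Minor introns as a class had higher inclusion levels in both knockdowns, while the median of major introns lay between 0.008 and 0.01 in each of the 9 libraries. The median level of 435 minor introns was 0.00867 ± 0.00058 (SD, n = 3) with shNC, 0.016 ± 0.003 (SD, n = 3) with shZCRB1-1 and 0.0203 ± 0.00058 (SD, n = 3) with shZCRB1-2. The median of 89042 major introns was 0.00933 ± 0.00058, 0.00867 ± 0.00115 and 0.00933 ± 0.00058 (SD, n = 3 each). Mean levels of minor introns were 0.0295 ± 0.00071, 0.0442 ± 0.00203 and 0.052 ± 0.00178 (SD, n = 3 each). Of the minor introns, 365 (83.9%) had a higher mean in the knockdowns and 67 (15.4%) a lower one; of the major introns, 48.3% were higher and 49.9% lower.

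The per-library class median, minor minus major, was higher by 0.61 on the log2 scale in the 6 knockdown libraries than in the 3 control libraries (two-sided exact permutation test, p = 0.0238, the smallest that 84 splits allow). Against shNC the difference was 0.52 for shZCRB1-1 and 0.70 for shZCRB1-2 (exact permutation p = 0.1 each, the smallest that 3 against 3 allows). The size depended on the scale, with 1.02 at a pseudocount of 0.001 and 0.12 at 0.1, and was 0.12 for all introns of the fixed list of minor-intron genes (exact permutation p = 0.0238 each). All 6 knockdown levels lay above all 3 control levels for 82 minor introns (18.9%) and 710 major introns (0.797%), where chance gives 1.19%. The median change of single minor introns was 0.41 on the log2 scale. Across 10000 random lists of major introns matched on level and length, medians ranged from -0.08 to 0.05.

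**Figure D1:**
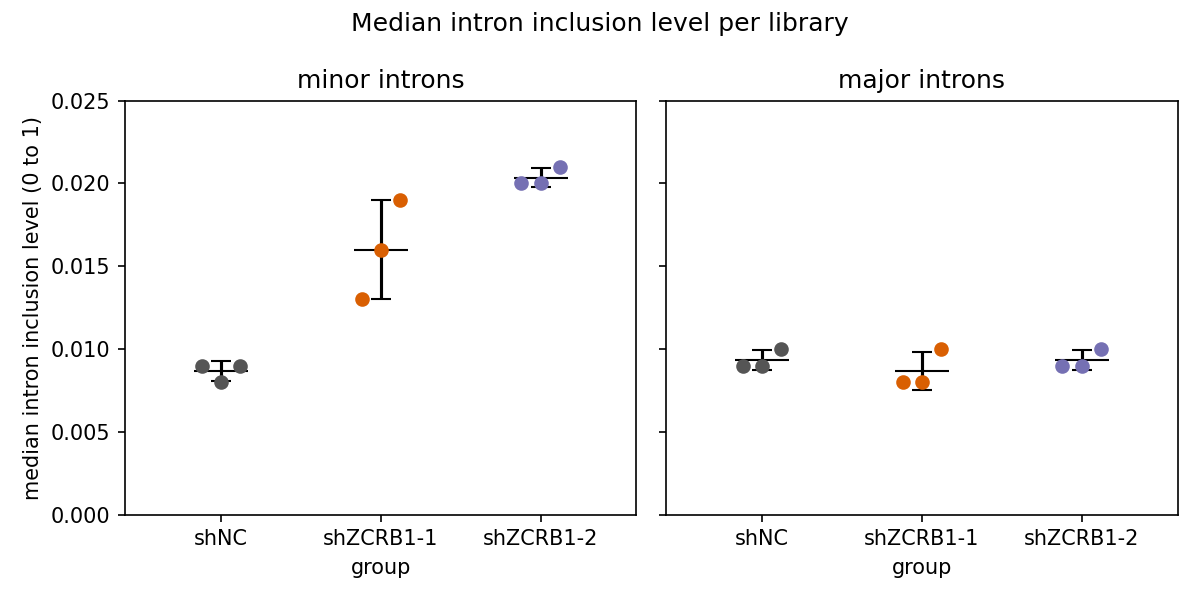
Median intron inclusion level (0 to 1) of minor introns (left) and major introns (right) in each library, by group; points are libraries and bars are the mean ± SD of 3. For minor introns the knockdown libraries lie between 0.013 and 0.021, above the control libraries at 0.008 to 0.009, while major introns lie between 0.008 and 0.01 in every group.

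Among minor introns past the FDR in both comparisons of the authors' deposited table, the largest rise in level was in HSBP1L1, intron 2 (chromosome 18, 79966679 to 79968088). Its level was 0.358 ± 0.0395 with shNC, 0.614 ± 0.0996 with shZCRB1-1 and 0.63 ± 0.0516 with shZCRB1-2 (SD, n = 3 each). On the log2 scale its rise of 0.78 was the smallest of the 12 introns taken by the rule, and that of C20orf194, at 2.82, the largest. CCDC43 intron 3 (chromosome 17, 44679044 to 44682002) went from 0.242 ± 0.0619 to 0.451 ± 0.0683 and 0.513 ± 0.032. In IFT80, which encodes a protein of intraflagellar transport, intron 2 (chromosome 3, 160381725 to 160384563) went from 0.0483 ± 0.0185 to 0.292 ± 0.0255 and 0.236 ± 0.107. The transcription factor gene E2F3 had 0.018 ± 0.00608, 0.0997 ± 0.0745 and 0.179 ± 0.0891 at intron 4 (chromosome 6, 20482921 to 20486688). TRAIP, a ubiquitin ligase gene, had 0.0387 ± 0.0168, 0.165 ± 0.0229 and 0.234 ± 0.0192 at intron 14 (chromosome 3, 49829226 to 49829457). Others of the 12 were in CEP170B, C20orf194, TMEM41B, CLCN6, USP21 and DERL2. The 12 introns lie in coding parts of their genes, and each passed the authors' FDR in both comparisons of the authors' deposited table. For HSBP1L1 intron 2, the authors' deposited table lists an FDR of 0.000497 with shZCRB1-1 and 1.45e-07 with shZCRB1-2.

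**Figure D2:**
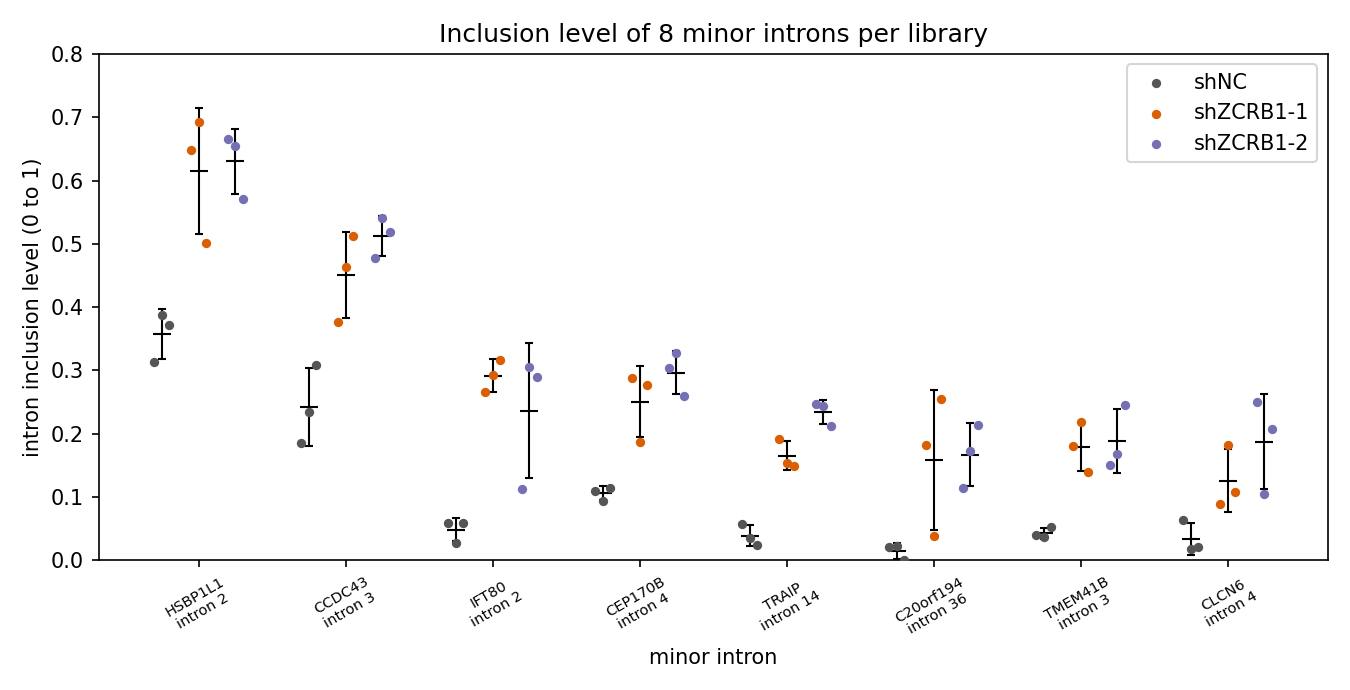
Inclusion level (0 to 1) of 8 minor introns in each library; points are libraries, coloured by group, and bars are the mean ± SD of 3. Mean levels in HSBP1L1 rise from 0.358 to 0.614 and 0.63, and for each of these introns the knockdown libraries lie above the control libraries.

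In the authors' deposited table, 71 of 453 minor introns were higher and 5 lower with shZCRB1-1, and 101 of 463 were higher and 2 lower with shZCRB1-2, at an FDR under 0.05. Of the major introns in the authors' deposited table, 759 of 95084 were higher and 1009 lower with shZCRB1-1, and 1103 of 97355 were higher and 922 lower with shZCRB1-2. With both hairpins, 63 of 435 minor introns were higher and 2 lower in the authors' deposited table, against 144 higher and 233 lower of 89042 major introns. Minor introns were thus 63 (30.4%) of 207 introns higher in both, and 0.486% of those tested (Fisher's exact test, two-sided, odds ratio 104.6, p = 9.81e-95). For each hairpin alone the share was lower, at 71 (8.55%) of 830 higher with shZCRB1-1 (odds ratio 23.1, p = 1.46e-65) and 101 (8.39%) of 1204 with shZCRB1-2 (odds ratio 24.4, p = 4.13e-93), by the authors' deposited table. The 2 minor introns that fell in the authors' deposited table, chosen for naming after their values were seen, were in POLR3C and EDC4. EDC4 intron 21 had levels of 0.114 ± 0.0138 with shNC, 0.055 ± 0.00529 with shZCRB1-1 and 0.06 ± 0.00265 with shZCRB1-2 (SD, n = 3 each). Another 37 minor introns were higher with shZCRB1-2 alone and 8 with shZCRB1-1 alone in the authors' deposited table; whether the hairpins differ at these was not shown, as the test between hairpins called none.

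The limma test, over all 89167 introns, called 0 introns for both hairpins against shNC, 0 for shZCRB1-1 and 0 for shZCRB1-2, with 5162, 4963 and 5014 at an unadjusted p under 0.05. Adjusted over the minor introns alone, limma called 60 higher and 4 lower for both hairpins, 18 higher and 1 lower for shZCRB1-1, and 62 higher and 2 lower for shZCRB1-2. For HSBP1L1 intron 2, limma's log2 change was 0.78 ± 0.11 (SE), with an adjusted p of 0.202 over all introns and 0.0061 over the minor introns alone. DERL2 intron 4 had a limma adjusted p of 0.0596 over the minor introns alone and did not pass. Over all introns the limma count for both hairpins was 31 with a pseudocount of 0.001 (9 higher and 22 lower), 13 without the trend (3 higher and 10 lower) and 1, higher, at mean levels from 0.02 to 0.98. It was 63, 41 and 63 when each shNC library was left out, and 60, 39 and 56 of these introns were lower. Adjusted over the minor introns alone, it was 25 higher without the first shNC library, 35 without the second, 34 without the third and 36 without the second shZCRB1-2 library. For shZCRB1-1 that count was 0 without its first library, 4 without the third, and 9 to 11 without any shZCRB1-2 library or without the first or second shNC library. For shZCRB1-2 it was 22 to 30 without any shNC library and 19 or 20 without any of its own.

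Major introns with the largest rises included a TMEM41B intron that shares its 5' splice site with the minor intron and ends 7 bases short of it on the other side. Its level was 0.418 ± 0.12 with shNC, 0.801 ± 0.0882 with shZCRB1-1 and 0.913 ± 0.0182 with shZCRB1-2 (SD, n = 3 each). LYRM9 intron 4 had 0.14 ± 0.0281, 0.42 ± 0.122 and 0.388 ± 0.114. The other 6 were in CCDC84, ZGLP1 (overlapping another gene, so uncertain), MIF4GD, PACRGL, GMFB and SRRT. Like the TMEM41B intron, that of GMFB shares the 5' splice site of a minor intron, and it ends 3 bases short of it. Such introns can share reads with the minor intron, and their class as major introns, as given, was not checked by sequence. The largest falls were in MSH5-SAPCD1 (overlapping SAPCD1), POMT1, LMO4, DBNDD1, SLC3A2 and AC005670.3. POMT1 intron 6, in a gene for protein O-mannosylation, had 0.766 ± 0.041, 0.469 ± 0.0671 and 0.365 ± 0.126 (SD, n = 3 each). LMO4 intron 1 had 0.466 ± 0.165, 0.142 ± 0.052 and 0.1 ± 0.0262. All 14 passed the authors' FDR in both comparisons of the authors' deposited table, and limma's adjusted p over all introns was above the threshold for each.

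Of the minor spliceosome list, only CCDC84, which encodes a minor spliceosome protein also called CENATAC, had introns past the authors' FDR in both comparisons of the authors' deposited table. A pair of its introns that end at the same base (chromosome 11, 119011938) moved in opposite directions. The one starting at 119011284 rose from 0.478 ± 0.0973 with shNC to 0.881 ± 0.0243 with shZCRB1-1 and 0.723 ± 0.0977 with shZCRB1-2, and the one starting at 119011312 fell from 0.121 ± 0.0384 to 0.0303 ± 0.00569 and 0.0463 ± 0.0301 (SD, n = 3 each). Overlapping introns can share reads, so these levels are not independent.

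E2F factors had 2 of 42 introns higher and 1 lower in the authors' deposited table. Both higher ones were minor introns, in E2F3 and E2F6; E2F6 intron 4 had 0.0103 ± 0.00681 with shNC, 0.043 ± 0.0115 with shZCRB1-1 and 0.0407 ± 0.00709 with shZCRB1-2 (SD, n = 3 each). The lower one was a major intron of E2F4. MAPK pathway kinases had 3 of 129 introns higher and 2 lower in the authors' deposited table, among them ARAF, higher, and MAPK12 (overlapping HDAC10, so uncertain), lower. ARAF intron 12, a minor intron, had 0.0117 ± 0.00611, 0.0317 ± 0.0111 and 0.0337 ± 0.00503. Minor-intron genes had 12 of 477 introns higher, 8 of them minor, and 5 lower in the authors' deposited table; ATG3 intron 11, in an autophagy gene, had 0.0257 ± 0.0159, 0.0913 ± 0.0467 and 0.09 ± 0.00656. Fisher's exact test on introns called in either direction, over the 13 lists, gave adjusted p of 5.41e-09 for minor-intron genes, 0.00311 for MAPK pathway kinases, 0.00516 for E2F factors and 0.0331 for SR proteins and CLK kinases. None of these 4 lists passed limma's camera test, with adjusted p of 0.508, 0.508, 0.877 and 0.653 with an estimated correlation. These lists overlap, since the E2F genes, for example, are members of more than 1.

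SR proteins and CLK kinases, which regulate splice site choice, had 0 of 169 introns higher and 4 lower in the authors' deposited table. TRA2A intron 1 fell from 0.202 ± 0.0278 with shNC to 0.128 ± 0.0201 with shZCRB1-1 and 0.12 ± 0.0193 with shZCRB1-2, and SRSF3 intron 3 from 0.0227 ± 0.00153 to 0.0133 ± 0.00208 and 0.0117 ± 0.00306 (SD, n = 3 each). The mitosis and kinetochore list had 1 of 146 higher (SPC24) and 2 lower (CDC20 and PLK1) in the authors' deposited table. Ribosomal proteins had 1 of 639 higher and 3 lower, including RPL28 and RPL22, and hnRNP genes 0 of 200 higher and 2 lower, including HNRNPH1, in the authors' deposited table. In the same source, the authors' deposited table, 1 intron was lower in each of the major spliceosome (SF3B3), exosome and integrator (INTS3), p53 target (BAX) and other cell type (FN1) lists, and DNA repair genes had 0 of 252 called.

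In limma's set tests for a shift in 1 direction, none of the 13 lists passed adjustment by camera or by fry. The smallest camera adjusted p was 0.688 and the smallest fry adjusted p 0.541. The minor introns as a class, in contrast, gave camera p = 4.14e-28, p = 1e-05 with an estimated correlation, and fry p = 2.43e-06. Fry's mixed test, for changes in either direction, gave unadjusted p from 1.15e-09 (minor-intron genes) to 0.223 (p53 targets) over the 13 lists. That test does not compare a list with other introns. Adjusted over the list alone, limma called 3 introns among E2F factors, 2 among MAPK pathway kinases, 2 among minor-intron genes, 1 in the minor spliceosome list, 1 among ribosomal proteins and 0 in each of the other 8 lists; over all introns it called 0 in every list. With 1 intron per gene, where minor introns were kept by construction, E2F factors and minor-intron genes passed camera (adjusted p = 0.00183 and 0.00138; 0.124 and 0.0416 with an estimated correlation).

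The hairpins were compared with each other directly. Minor introns had a per-library class median higher by 0.18 on the log2 scale with shZCRB1-2 than with shZCRB1-1 (exact permutation p = 0.1, the smallest possible). For single introns limma called 0 of 89167, with 4804 at an unadjusted p under 0.05, and 0 when adjusted over the minor introns alone; without the trend it called 1. Changes of minor introns under the hairpins had a covariance of 0.326, against 0.0865 for simulated unchanged groups sharing the same controls, and a correlation of 0.749 against 0.510. For major introns the covariance was 0.0993 against 0.0683, and the correlation 0.505 against 0.499. At limma's unadjusted p under 0.05, 73 minor introns were higher with both hairpins, against 1.95 in the simulated groups and 26.7 for independent lists, and 5 were lower, against 3.25 and 0.138. For major introns 515 were higher, against 443 in the simulated groups and 51.9 for independent lists, and 1125 were lower, against 741 and 82.3. By the authors' deposited table, 63 minor introns were higher with both hairpins where independent lists would share 16.3, and 144 major introns where they would share 8.63. The simulated groups leave out real effects and the independent lists leave out the shared controls; the authors' calls were not simulated. The 3 control libraries were not split, being too few to give each hairpin at least 2 of its own. Part of the excess over independent lists may therefore come from the shared control libraries. The simulated groups share these controls by design, so within that model shared control noise does not account for the excess over them.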

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

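The introns named here were picked after the data were seen, because the authors' deposited table called them in opposite directions with the 2 hairpins. A 26-base intron of XBP1 (chromosome 22, 28796122 to 28796147) had levels of 0.737 ± 0.0442 with shNC, 0.849 ± 0.0302 with shZCRB1-1 and 0.649 ± 0.0423 with shZCRB1-2 (SD, n = 3 each), a difference between the hairpins of -0.2, and every knockdown level lay on its group's side of the control mean. RPL17 intron 1 had 0.835 ± 0.0185, 0.776 ± 0.00361 and 0.883 ± 0.0129 (SD, n = 3 each), a difference of 0.107 in the other direction. In limma's test between the hairpins both had an adjusted p of 0.497 over all introns and did not pass. The XBP1 intron is a major one only by the class given. Whether a spliceosome removes it was not tested, so its levels are not read as a spliceosomal effect.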

How the results depend on the processing

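The limma count for both hairpins, 0 over all introns, became 31 with a pseudocount of 0.001, and, among settings chosen after seeing the data, 13 without the trend and 1 at mean levels from 0.02 to 0.98; leave-one-out counts ranged from 0 to 63. For shZCRB1-1 it was 6 without the trend; for shZCRB1-2, 6 without the trend and 1 at mean levels from 0.02 to 0.98; between the hairpins, 1 without the trend. All other settings gave 0, robust empirical Bayes included, and the cause of these differences was not tested. The counts of minor introns higher when adjusted over minor introns alone, all added after seeing the data, were 60, 18 and 62 for both hairpins, shZCRB1-1 and shZCRB1-2. They became 14, 8 and 17 with a change of at least 0.1 in level, 13, 0 and 13 at a threshold of 0.01, and 35, 0 and 41 on the untransformed level. Without the trend, 92 and 50 were called for both hairpins and shZCRB1-1. For shZCRB1-1 the count was 37 and 11 with pseudocounts of 0.001 and 0.1, 36 with robust empirical Bayes, 35 on log2 of level over 1 minus level and 35 at mean levels from 0.02 to 0.98. Leave-one-out counts ranged from 25 to 51, 0 to 19 and 19 to 61. The 207 introns higher in both hairpins in the authors' deposited table became 93 at an FDR under 0.01 and 43 with a change of at least 0.1, and the 235 lower ones 64 and 49. The minor share stayed above that of all introns tested in each setting, from 5.67% to 50.5%, and was 70.6% against 3.53% tested with 1 intron per gene, where minor introns were kept by construction; all introns of the fixed list, most of them major, made up 5.8% against 0.533%. The class difference of 0.61 kept its direction in each setting, but its size was 0.12 for all introns of the fixed list of minor-intron genes and, among settings chosen after seeing the data, 1.02 and 0.12 with pseudocounts of 0.001 and 0.1, 0.42 as the median of single-intron changes and 0.76 at mean levels from 0.02 to 0.98; leave-one-out values ranged from 0.593 to 0.654, with an exact permutation p of 0.0714 when a control library was left out, the smallest that the remaining splits allow. Gene lists passing camera went from 0 to 2 with 1 intron per gene, and 1 of these held with an estimated correlation (E2F factors had an adjusted p of 0.124). None of the 26 introns named for rises and falls changed direction with either pseudocount or any library left out. Except in E2F3 and DERL2, all 6 knockdown levels of each lay on the same side of all 3 control levels. Their direction could therefore not change in these settings, and this is no evidence of stability. No paired analysis was possible because the levels of a group carry no replicate number. Not run were DESeq2, depth minimums, the stricter sequence rule, the deepest intron per gene, flags of intron quality and gene expression, for want of counts, depths, sequence or flags among the values used here.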

Other observations

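The tests in this part were chosen after the results they bear on had been seen, apart from the fixed comparison of class medians. Major introns just downstream of a minor intron were more often called higher than distant introns of the same genes. Of 867 major introns within 500 bases of a minor intron, 13 (1.5%) were higher with both hairpins in the authors' deposited table, against 5 of 3361 (0.15%) more distant major introns of the same genes (Fisher's exact test, two-sided, p = 3.2e-06, 9.6e-06 adjusted over 6 comparisons). Those 13 included introns of XPO4, XPO7, SPC24, RAPGEF1, INSIG1 and TMEM181. XPO4 intron 21 had levels of 0.0127 ± 0.0125 with shNC, 0.0657 ± 0.0556 with shZCRB1-1 and 0.067 ± 0.028 with shZCRB1-2 (SD, n = 3 each). Its knockdown levels did not all lie above its control levels. In the authors' deposited table, 11 of 426 neighbours that lay only downstream of a minor intron were higher (adjusted p = 5.02e-07 against distant introns) and 1 of 436 that lay only upstream (adjusted p = 0.623), and these sides differed (Fisher's exact test, p = 0.00293, 0.00586 adjusted). The remaining intron, in SPC24, was among 5 with a minor intron on both sides. The mean log2 change was above that of distant introns by 0.18 for neighbours only downstream and by 0.10 for those only upstream (exact permutation p = 0.0238 each, 0.0357 adjusted).

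Higher retention of minor introns was weighed against 2 technical explanations and chance. Unspliced RNA or DNA carried into the knockdown libraries would raise major introns too, and their median log2 change was -0.009. A low level or short length of minor introns was tested with lists of major introns matched on both, and 0 of 10000 reached the minor median. For both hairpins, 1 of 100 splits of the libraries, the real one, called as many minor introns higher as the 60 observed (limma, adjusted over the minor introns alone). There are only 84 ways to choose the 3 control libraries, and this count was added after the data were seen. Chance was therefore made less likely but not excluded. The highest other split called 52 and kept the same 3 control libraries, mixing only the hairpins, while each of the other 98 called 0. For each hairpin alone the 10 splits are too few for a share under 0.05: the real values were 18 and 62, each reached by 1 split, and the highest others 0 and 1. A biological effect of ZCRB1 knockdown on minor introns remains a hypothesis that may account for the class difference, while differences in depth stay open.

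Over all introns limma called 0 in the real split, a count that every split reaches whatever the data hold, so the splits say nothing about chance for it. All 100 splits for both hairpins, and all 10 for shZCRB1-1, for shZCRB1-2 and for the difference between the hairpins, therefore reached it, with 13, 1, 0 and 0 introns in the highest other split.

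The rise of neighbouring major introns was tested against more unspliced RNA from the whole gene. The mean log2 change was 0.12 for neighbours and -0.02 for distant introns of the same genes (difference 0.14, exact permutation p = 0.0238, the smallest possible, and 0.0357 adjusted over 6 comparisons). Distant introns differed from major introns of other genes by 0.003, which argues against that explanation. Retention that extends from a retained minor intron to its neighbours is a candidate explanation: the change of a neighbour had a Spearman rho of 0.146 with that of its minor intron across 867 introns (permutation p = 2e-05, 8e-05 adjusted over 4 correlations), against 0.005 for distant introns (p = 0.75). Introns are not independent replicates, and depth shared by neighbours was not analysed here.

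Major introns that overlap a minor intron moved more often than others. With either hairpin, 14 of 82 (17.1%) were lower and 8 (9.76%) higher in the authors' deposited table, against 1.78% and 1.83% of 88960 other major introns. Of the 54 that share neither splice site with the minor intron, 13 (24.1%) were lower and 1 (1.85%) higher; of the 19 that share its 5' splice site, 1 was lower and 6 (31.6%) higher, also in the authors' deposited table. PFDN5 had an intron of the former kind with levels of 0.771 ± 0.0417 with shNC, 0.55 ± 0.0519 with shZCRB1-1 and 0.564 ± 0.102 with shZCRB1-2, and GMFB one of the latter kind at 0.079 ± 0.089, 0.266 ± 0.0405 and 0.317 ± 0.0343 (SD, n = 3 each). A high control level of overlapping introns could produce more falls, but among other major introns with a control level of at least 0.5 only 3.52% were lower, against 22.8% of 57 overlapping ones (Fisher's exact test, p = 8.85e-08). Some genes, SPCS2 and TM2D1 among them, gave more than 1 lower intron with a shared end, so these are not independent. The match on level was coarse, as the median control level of those sharing neither splice site was 0.956. Several of the lower introns, among them those of SPCS2 and NCBP2, had both ends outside the minor intron, while that of SNRPE lay inside it. Use of other splice sites, inside or around minor introns, and the sharing of reads between overlapping introns both stay open.

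The change of a minor intron showed no clear relation to its length (Spearman rho across 435 introns -0.025, permutation p = 0.61) or to its control level (rho 0.015, p = 0.75), with adjusted p = 0.75 for both over the 4 correlations computed across introns. The shNC levels enter both the change and the control level, and the log2 scale understates changes near 0. The rho with control level therefore cannot decide whether the change depends on it.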
